A study of Mus musculus with 4 samples.

How the data were processed

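Hi-C libraries of whole mouse uterus were prepared with the Arima kit, per the labels' protocols. Adult C57BL/6J females were ovariectomised, rested for 10 to 14 days, injected, and the uterus was frozen 1 h later. The injection was 100 ul of saline into the abdominal cavity, or 1 mg of progesterone in 100 ul of sesame oil under the skin. Whether a library came from 1 animal or from a pool, and whether replicates were separate animals, is not given in the sources used here.

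For each library the authors deposited a list of loops: 6 columns of positions with no header, for the chromosome, start and end of both anchors. The deposited positions are in bases on mm10, per the submitters' processing notes, which also name Juicer 1.5.6. The lists hold anchors of 5, 10 and 25 kb, all loops lie within a chromosome, and starts count from 0 and were written from 1 here. The loop caller and its thresholds are not given in the sources used here. No contact counts, expected counts or false discovery rates were used here, so the depth of each library is unknown, and the number of loops in a list is no substitute for it.

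Libraries were grouped by the labels: 2 wild-type vehicle, 1 wild-type progesterone and 1 ERα knockout vehicle library. The gene lists, the comparisons and the first set of alternative settings were fixed before the data were examined; the settings added later are named in the closing section. A loop counted as shared when a loop of the other list overlapped both anchors after 10 kb was added to each side of each anchor. Chance overlap came from 100 random shifts along the chromosome with loop length kept. Loops that differed were those in both vehicle lists, in replicate 2 coordinates, and not in the other list, and those in the other list and in neither vehicle list; the same counts between the vehicle lists were the baseline. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only, since neighbouring loops are not independent.

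Genes came from a RefSeq table of GRCm38.p6, the assembly behind mm10, with 21631 protein-coding genes and no strand. The planned start site could therefore not be told from the gene end, and a gene was placed at an anchor when its start or its end lay inside. The 13 lists hold 282 entries and 266 distinct genes, all matched, and some genes are in more than 1 list. Each list was ranked among 10000 random lists of as many genes, matched on 5 classes of the number of genes within 100 kb. Lists at loops that differ were compared with the other genes at anchors of the 3 lists by 2-sided Fisher exact tests with Benjamini-Hochberg adjustment over 13 lists and both directions.

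The genes named were, in each direction of each comparison, up to 10 genes of the fixed lists and up to 5 of any protein-coding genes, up to 10 list genes at loops in all 4 lists, and always Esr1, Pgr, Igf1, Greb1, Ihh and the Hoxa and Hoxd clusters. A gene that this rule names is not reported here. Other genes named as examples of a list or by position were chosen after their values were seen. The planned order by loop strength needs contact counts; the order used instead was most loops of the class, then finest bin, then symbol, and was set before the values per gene were seen.

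The overlap step was tested on simulated data made from the 16387 loops of vehicle replicate 2, and recovered 100% of loops left in place and 0.468% of loops moved away. Of random gene lists, 6.5% were above the 95th percentile, and 94% of lists drawn at 3 times the odds were. The Fisher step on 7428 genes called 1.5% of random lists and 81% of lists at 3 times the odds. Those calls used an unadjusted p under 0.05 and lists larger than most of the lists tested here. The 81% therefore does not carry over to the adjusted tests, which can miss differences of that size. In that simulation genes were marked as differing at random, so the number of loops per gene played no part. Relative depth, loop strength, the filter on depth, stricter calling thresholds and the orientation of CTCF motifs, all planned, need values or sequence not used here and were left out. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.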

Results

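Chromatin loops were mapped by Hi-C, which joins and sequences DNA segments that lie close together in the nucleus, in whole uteri of ovariectomised mice on the mm10 genome. The tissue was taken 1 h after injection. The 4 libraries analysed here were 2 of wild-type uterus after saline vehicle (replicates 2 and 3), 1 of wild-type uterus after 1 mg of progesterone (replicate 2), and 1 of uterus lacking estrogen receptor alpha (ERα, encoded by Esr1) after saline vehicle (replicate 1). Progesterone was given under the skin in sesame oil and saline into the abdominal cavity, so that comparison also differs in carrier and route. Estradiol samples were not analysed here. The lists held 16387 loops in vehicle replicate 2, 9385 in vehicle replicate 3, 11752 after progesterone and 21829 in the ERα knockout, with median loop lengths of 185, 200, 190 and 150 kb. Vehicle replicate 2 thus had 1.75 times the loops of vehicle replicate 3, and the knockout had 1.33 and 2.33 times as many as those libraries. The lists give positions only, so the sequencing depth and the strength of each loop are unknown, and an unlisted loop was not called rather than shown to be absent. Progesterone and the knockout have no replicate, so no test was made between conditions. Intervals of shares are exact binomial 95% intervals, and all intervals cover counting error only.

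**Figure D1:**
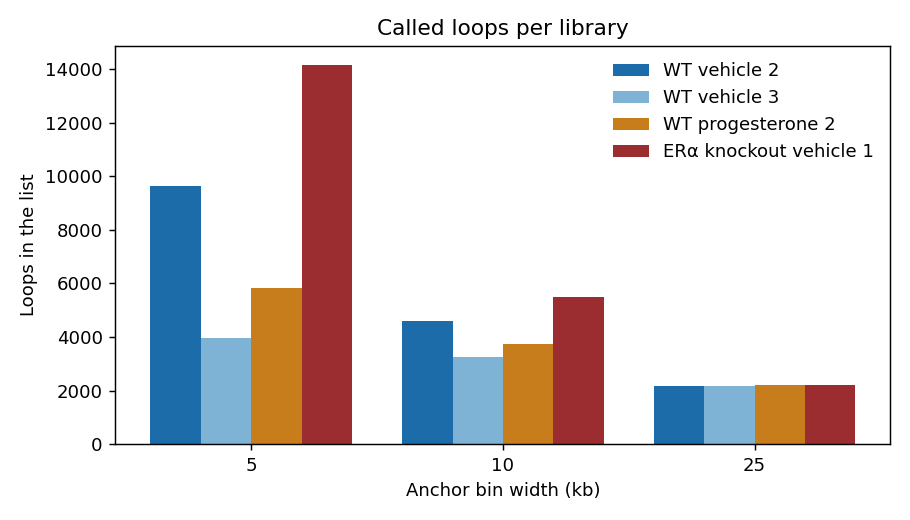
Number of called loops (vertical axis) by anchor bin width in kb (horizontal axis) in each of the 4 libraries, 1 bar per library. The lists differ most at 5 kb, from 3953 loops in vehicle replicate 3 to 14153 in the ERα knockout, and hold 2173 to 2203 loops each at 25 kb.

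Most loops of the shorter lists were found again in the longer ones, among them loops at genes of the uterine stroma and of Müllerian duct patterning. With 10 kb added to the anchors, 85.7% (85.0 to 86.4) of the vehicle replicate 3 loops were in vehicle replicate 2, 78.4% were in the progesterone list and 85.0% in the knockout list. Of the progesterone loops, 81.0% were in vehicle replicate 2 and 81.0% in the knockout, and 74.3% of the vehicle replicate 2 loops were in the knockout. Loops shifted at random along their chromosomes gave a mean overlap of 1.38% for the pair of vehicle lists. A total of 6388 vehicle replicate 2 loops were called in all 4 libraries. Among the fixed gene lists, Snai2, which encodes a zinc finger repressor, had the most such loops, with 5. Col3a1, a fibrillar collagen gene, Jun, an AP-1 subunit gene, and Osr1, a transcription factor gene of the urogenital mesenchyme, had 4 each. Bhlhe40, Fosl2, Hoxa13, Klf6, Myc and Nr2f2 had 3 each. Examples are a 565 kb loop that joins chromosome 1 positions 44745001 to 44750000 with 45310001 to 45315000 at Col3a1, and a 425 kb loop that joins chromosome 12 positions 9570001 to 9575000 with 9995001 to 10000000 at Osr1.

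Genes that respond early to estrogen, genes of progesterone response, uterine patterning genes, stromal markers and steroid receptor genes lay at loop anchors more often than random genes of like surroundings in each of the 4 libraries. Of 39 early estrogen genes, 29 had a start or end in an anchor in vehicle replicate 2, 28 in vehicle replicate 3, 28 after progesterone and 32 in the knockout, against means of 14.4, 10.2, 11.9 and 17.6 in 10000 random lists matched on gene density. The group was above every random list, or nearly so, in each library (100th percentile as rounded), and 23 of its members were at anchors in all 4 libraries, including Igf1, a growth factor gene, Ccnd1, Vegfa and Klf4. Of 33 patterning genes, 24, 23, 21 and 26 were at anchors in the same order of libraries (100th percentile in each), and Hoxd9 to Hoxd13, Wnt5a, Wnt7a and Tbx3 were among the 17 at anchors in all 4. The Hoxa and Hoxd genes of this list are neighbours that can share an anchor, while random genes were drawn separately. The percentile of the patterning genes may therefore be too high. Stromal markers numbered 12, 12, 11 and 14 of 14 (99.98th to 100th percentile), with Col1a1, Pdgfra, Twist2 and Lum among the 10 found in all 4. Progesterone response genes numbered 19, 21, 20 and 27 of 36 (97.7th to 100th percentile), and Bmp2, Gata2, Cited2 and Zbtb16 were among the 15 in all 4. Steroid receptor and coregulator genes numbered 14, 13, 11 and 16 of 23 (96.7th to 99.9th percentile), with Esr2, Ncoa2, Ncor1 and Nrip1 in all 4. In the progesterone library this last group was at the 91.6th percentile when gene bodies were used and random lists were also matched on gene length.

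Markers of muscle and of the other cell types of the uterus gave mixed counts. Smooth muscle markers, such as Acta2, Smtn and Myl9, numbered 10, 7, 7 and 8 of 13, above the 95th percentile in the 3 wild-type libraries and at the 88.6th in the knockout. Genes of architectural proteins such as cohesin regulators numbered 7, 4, 4 and 10 of 14, and only the knockout value was above the 95th percentile, at 97.8; with gene ends within 10 kb of an anchor it was at 89.5. Pds5a and Pds5b were at anchors in all 4 libraries, and Ctcf and Med12 in the knockout alone. Epithelial markers numbered 2, 3, 2 and 7 of 16, and the keratin genes Krt7, Krt8, Krt18 and Krt19 were at no anchor in any library. Endothelial markers numbered 4, 2, 0 and 3 of 11, and immune markers 2, 2, 1 and 1 of 13. Genes of late estrogen response numbered 9, 6, 7 and 12 of 27, close to the random means of 9.37, 6.45, 7.53 and 11.9. As outside groups, hepatocyte genes numbered 5, 5, 3 and 4 of 21 and neuronal genes 10, 5, 9 and 9 of 21, none of them above the 95th percentile. In each library 6 of the 13 lists were above that percentile, where chance gives about 1 in 20. Below the 5th percentile were epithelial markers in vehicle replicate 2 (3.16), endothelial markers after progesterone (1.21), and immune markers (0.475) and hepatocyte genes (0.835) in the knockout. Chance also puts about 1 in 20 there, and the counts are small. Endothelial markers were at the 54.5th and 33.7th percentile in vehicle replicates 2 and 3.

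**Figure D2:**
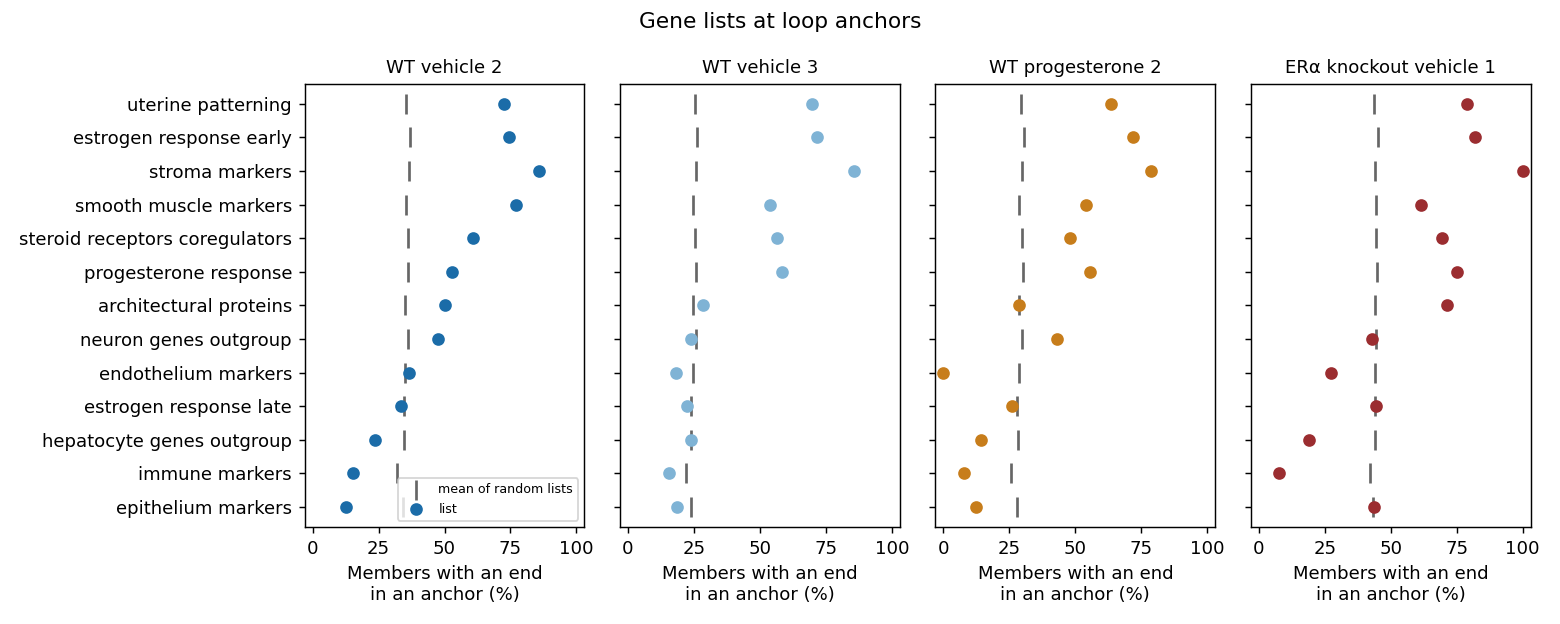
Percent of the members of each of 13 gene lists (rows) with a gene start or end in a loop anchor (horizontal axis), 1 panel per library; points are the list and ticks the mean of 10000 random lists matched on gene density. Early estrogen, patterning, stromal, progesterone response and steroid receptor genes lie to the right of the ticks in all 4 panels, and in the progesterone panel 0 of 11 endothelial markers are at anchors.

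Among the genes chosen in advance for the study of estrogen and progesterone response, Esr1, Pgr, Greb1 and Igf1 each had loops matched in all 4 lists. In this paragraph a loop touched a gene when an anchor overlapped any part of it. By gene start or end alone, vehicle replicates 2 and 3, progesterone and the knockout had 1, 2, 0 and 1 loops at Esr1. Pgr then had 0, 1, 3 and 0, Greb1 0, 1, 1 and 0, and Igf1 4, 2, 1 and 5. Esr1 (chromosome 10, 4611989 to 5005633) was touched by 4 loops in vehicle replicate 2, 5 in vehicle replicate 3, 4 after progesterone and 9 in the knockout. An 85 kb loop within the gene, from 4630001 to 4635000 to 4715001 to 4720000, and a loop from about the same inner anchor to 5140001 to 5150000, beyond the gene end, were in all 4 lists, and 6 of the 9 knockout loops were in no other list. The deletion in Esr1 itself is not readable from loop positions, so these loops are no check of the knockout label. Pgr, the progesterone receptor gene (chromosome 9, 8898900 to 8968611), was touched by 5, 5, 5 and 4 loops. A 260 kb loop from 8700001 to 8960001 was in all 4 lists, and a 200 kb loop from 8700001 to 8900001 was in the 3 wild-type lists but not in the knockout list. A loop from 8730001 to 8900001 was in the knockout, vehicle replicate 3 and progesterone lists. Greb1, an estrogen-induced gene (chromosome 12, 16670615 to 16801394), was touched by 5, 5, 4 and 3 loops, of which the 35 kb and 90 kb loops that start at 16715001 were in all 4 lists. Igf1 (chromosome 10, 87858265 to 87937047) was touched by 5, 2, 2 and 6 loops, and a 445 kb loop from 87855001 to 88300001 was matched in all 4.

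The Hoxa and Hoxd clusters, which pattern the reproductive tract, were touched by 14, 11, 12 and 17 loops and by 15, 9, 12 and 19 loops. A 3050 kb loop from 49200001 to the Hoxa13 end of the Hoxa cluster at 52250001 on chromosome 6 was in all 4 lists. Loops from 50810001 and 51170001 ended at 52225001, in Hoxa9, in vehicle replicate 2 and after progesterone, and at 52240001, over the facing ends of Hoxa10 and Hoxa11, in vehicle replicate 3 and the knockout. Hoxa10 had ends in 0, 4, 1 and 7 loops and Hoxa11 in 0, 4, 0 and 5. This difference ran between the vehicle replicates and was seen after the positions were examined.

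**Figure D3:**
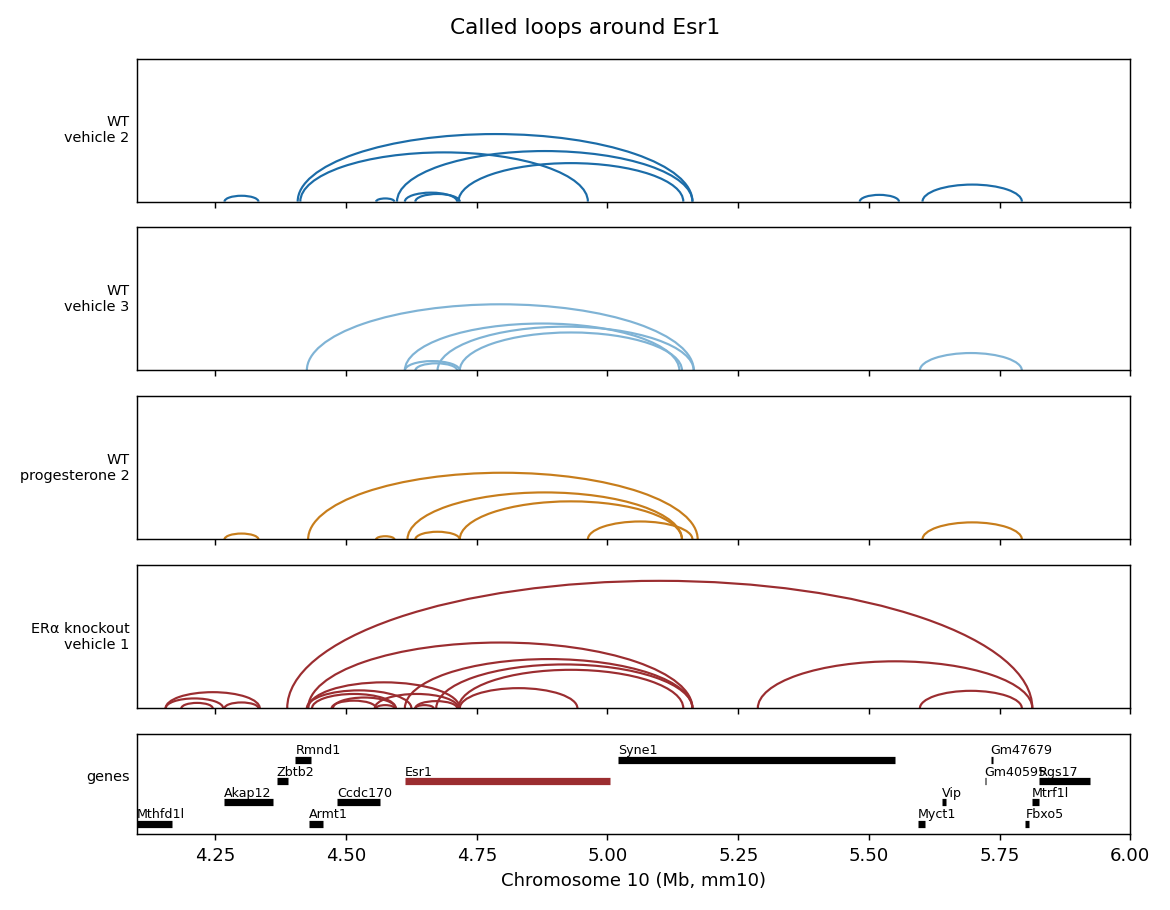
Called loops as arcs around Esr1 in each of the 4 libraries, with protein-coding genes as bars, over chromosome 10 from 4.1 to 6.0 Mb (horizontal axis, mm10); arc height grows with loop length and carries no strength. The 85 kb loop within Esr1 is in all 4 rows, and loops within 500 kb of the gene number 12, 8, 10 and 24 in vehicle replicates 2 and 3, progesterone and the knockout.

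The progesterone library was compared with the vehicle libraries to find loops that differ 1 h after the hormone. From here on, the loops of a gene are those with its start or end in an anchor. Ihh, the progesterone-induced Indian hedgehog gene of the uterine epithelium, had 2 loops in each vehicle list and 0 after progesterone. These loops join the gene (chromosome 1, 74945315 to 74951672) with 75015001 to 75020000, 70 kb away, and with 75250001 to 75255000, 305 kb away. Klf6, an early estrogen gene, was at 3 loops of the progesterone list that were in neither vehicle list, and Cebpd, Cited2, Myc and Twist1 were at 2 each. In vehicle replicates 2 and 3 and progesterone, all loops of these genes numbered 5, 6 and 8 for Klf6, 3, 3 and 3 for Cebpd, 10, 2 and 7 for Cited2, 12, 4 and 9 for Myc, and 5, 1 and 3 for Twist1, so for the last 4 the progesterone total lay within the vehicle range. In total, 1214 of the 8061 loops called in both vehicle lists were not called after progesterone (15.1%, 14.3 to 15.9), and 1742 of the 11752 progesterone loops were in neither vehicle list (14.8%, 14.2 to 15.5). By the same measure, vehicle replicate 2 lacked 5.99% of the loops called in both vehicle replicate 3 and progesterone. Vehicle replicate 3 lacked 28.2% of those called in both vehicle replicate 2 and progesterone, so the progesterone value lay between them. The short list of vehicle replicate 3 in itself raises its share, so lying between is no test of an effect of progesterone. Vehicle replicate 3 lacked 37.4% of the progesterone loops and 50.8% of the vehicle replicate 2 loops, and vehicle replicate 2 lacked 19.0% of the progesterone loops and 14.3% of the vehicle replicate 3 loops. Without vehicle replicate 2 the counts of 1214 and 1742 became 2027 and 4391, and without vehicle replicate 3 they became 6850 and 2229. With 0 kb added to the anchors the shares of 15.1% and 14.8% became 32.3% and 32.1%, and for 10 kb loops alone 43.3% and 50.8%.

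Loops in both vehicle lists and not in the progesterone list touched Hoxa9, Nr2f2 and Cebpd at 2 loops each besides Ihh. Of these 1214 loops, 315 (25.9%) had a progesterone loop within 25 kb of both anchors, and the Hoxa9 example from 51860001 to 52220001 on chromosome 6 had one from 51875001 to 52220001. They touched Cebpb, a leucine zipper gene required for decidualisation, Esr1, Gadd45g, Hoxa13, Jun and Myh11, a smooth muscle myosin gene, at 1 each. The Esr1 loop was 100 kb long, from 4610001 to 4615000 at the gene edge to 4710001 to 4715000 inside it. The Jun loop spanned 820 kb (chromosome 4, 95050001 to 95055000 and 95870001 to 95875000), and Jun still had 8 loops after progesterone. The Nr2f2 loop spanned 865 kb, and that gene had 12, 4, 5 and 14 loops in the 4 libraries. Outside the lists, Arsk, Dhps and Dipk1a had 2 such loops each and no gene end in a progesterone loop, against 2 or 3 loops in each vehicle library; 1 progesterone loop touched the body of Dipk1a. Bambi and Denr had 2 such loops and 2 loops after progesterone.

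Loops of the progesterone list in neither vehicle list touched Cdkn1c, a cyclin-dependent kinase inhibitor gene, which had 0, 0, 1 and 2 loops in the 4 libraries, and Zfp143, which had 0, 0, 1 and 5. Lmod1, Lum and Ncoa1 were at 1 such loop each. The Klf6 example spanned 610 kb (chromosome 13, 5250001 to 5260000 and 5860001 to 5870000), the Cited2 example 850 kb and the Myc example 310 kb. Outside the lists, Asph, Pxk, Rdh10, Acss3 and Dnajc2 had 3 such loops each; Rdh10, a retinol dehydrogenase gene, had 5, 3, 6 and 6 loops overall.

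By list, 9 of 32 early estrogen genes at anchors were at loops seen in both vehicle lists and not after progesterone (28.1%, against 9.70% of other genes, odds ratio 3.64, 2-sided Fisher exact p = 0.00275, Benjamini-Hochberg adjusted p = 0.0715). Progesterone response genes were at progesterone loops in neither vehicle list in 8 of 24 cases (33.3% against 15.3%, Fisher exact adjusted p = 0.214) and stromal markers in 5 of 13 (38.5% against 15.4%, adjusted p = 0.245). In the opposite direction, progesterone response genes were at vehicle loops not called after progesterone in 6 of 24 cases (25% against 9.73%, Fisher exact adjusted p = 0.214). None of the 26 Fisher tests passed an adjusted p of 0.05, and 5 had an unadjusted p under 0.05. The test compares those libraries, not the conditions. A gene counted as differing when any of its loops did, so genes with many loops count more often, and loops per gene were not matched. Neighbouring genes, such as those of the Hox clusters, can also share a loop. With gene ends within 10 kb of an anchor, a setting added after the data were seen, 4 lists passed, of which progesterone response genes at progesterone loops in neither vehicle list (14 of 31, adjusted p = 0.0155) and patterning genes at vehicle loops not called after progesterone (11 of 31, adjusted p = 0.0229) had the lowest values by the same exact test; the other two were hepatocyte genes and stromal markers.

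The knockout library was compared with the vehicle libraries to find loops that differ without ERα. A 1125 kb loop between Zfp444 and Zfp787 at 6150001 and Clcn4 and Vmn2r29 at 7275001 on chromosome 7 was in both vehicle lists and not in the knockout list. Clcn4 and Vmn2r29 each had 5 loops in vehicle replicate 2, 3 in vehicle replicate 3, 2 after progesterone and 0 in the knockout. In the other direction, Fbxo5 had 8 loops in the knockout and 0 in each wild-type library. Fbxo5 (chromosome 10, 5799158 to 5805465) lies near Esr1 (4611989 to 5005633), the gene altered in the knockout. At Fbxo5 a local effect of the altered locus therefore cannot be told from loss of ERα. Of the 8061 loops in both vehicle lists, 808 were not called in the knockout (10.0%, 9.38 to 10.7). By the same measure, vehicle replicate 2 lacked 7.95% of the loops called in both vehicle replicate 3 and the knockout. Vehicle replicate 3 lacked 40.4% of those called in both vehicle replicate 2 and the knockout, so the knockout value lay between them. The list of vehicle replicate 3, with 9385 loops, is shorter than the 12175 loops looked for, which in itself raises its share. Lying between the vehicle replicates is therefore no test of an effect of the knockout. The knockout list, though the longest, lacked a larger share than vehicle replicate 2. Of the 21829 knockout loops, 8856 were in neither vehicle list (40.6%, 39.9 to 41.2). Vehicle replicate 3 lacked 63.3% of the knockout loops, against 50.8% of the vehicle replicate 2 loops, and vehicle replicate 2 lacked 44.1% of the knockout loops, against 14.3% of the vehicle replicate 3 loops. Without vehicle replicate 2 the counts of 808 and 8856 became 1406 and 13817, and without vehicle replicate 3 they became 4212 and 9632. The share of 10.0% became 25.5% with 0 kb added to the anchors, 5.55% with 25 kb added and 51.9% for 10 kb loops alone, and 6.01% when midpoints were matched. The share of 40.6% became 52.2% with 0 kb added, 34.8% with 25 kb added and 68.3% for 10 kb loops alone.

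Loops in both vehicle lists and not in the knockout list touched Esr1, Hoxd9, Hoxd11, Igf1, Ihh, Jun, Klf6, Lum and Nrip1 at 1 loop each. Of the 808 loops, 47.3% had a knockout loop within 25 kb of both anchors. The Esr1 loop was the 100 kb loop described for progesterone, and the Ihh loop the 70 kb one; the 305 kb Ihh loop was matched in the knockout. The Jun loop was again the 820 kb one. These loops share the same vehicle libraries with the progesterone comparison, so their appearance in both is not independent. The Igf1 loop spanned 205 kb from 87650001 to 87855001, and the knockout list held a loop from 87665001 to 87855001 that lay just outside the matching distance. The Nrip1 loop spanned 170 kb and the Hoxd11 loop 1095 kb (chromosome 2, 74685001 to 74690000 and 75780001 to 75785000). Nrip1, a nuclear receptor corepressor gene, had 6, 3, 4 and 8 loops overall. Outside the lists, Zfp787 was at 3 such loops, but also at 4 knockout loops in neither vehicle list, and had 4, 4, 4 and 6 loops overall. Asrgl1 and B9d1 were at 2 such loops and had 2, 2, 2 and 1 and 4, 4, 3 and 3 loops overall.

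Loops of the knockout list in neither vehicle list touched Cited2, Myc and Ncoa2, a steroid receptor coactivator gene, at 6 each. They touched Sox4, Zfp143, Hoxd9 and Hoxd10 at 5 and Klf6, Nr2f2 and Hoxd11 at 4. Ncoa2 had 2, 2, 2 and 8 loops in the 4 libraries and Sox4 had 5, 3, 4 and 9. Zfp143 had 0, 0, 1 and 5 loops, Hoxd10 3, 2, 3 and 7, Klf6 5, 6, 8 and 10, Myc 12, 4, 9 and 16, Hoxd9 8, 4, 6 and 10, Nr2f2 12, 4, 5 and 14, Cited2 10, 2, 7 and 10, and Hoxd11 5, 3, 2 and 5. Outside the lists, Fbxo5, which encodes an inhibitor of the anaphase-promoting complex, and the neighbouring Mtrf1l were at 8 such loops. Eml6, Gtdc1 and Zfp444 were at 7; no wild-type loop held an end of Eml6, but 3, 1 and 2 touched the gene body. An example at Fbxo5 spans 1425 kb (chromosome 10, 4375001 to 4400000 and 5800001 to 5825000) and reaches Zbtb2. Its span includes all of Esr1.

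By list, 6 of 34 early estrogen genes at anchors were at loops in both vehicle lists and not in the knockout list (17.6%, against 4.81% of other genes, odds ratio 4.24, 2-sided Fisher exact p = 0.00533, adjusted p = 0.139), and 3 of 14 stromal markers were (21.4% against 4.83%, adjusted p = 0.180). At loops of the knockout in neither vehicle list were 18 of 29 progesterone response genes (62.1%), 18 of 28 patterning genes (64.3%) and 17 of 34 early estrogen genes (50%), against 55.8% of other genes. The lowest p values in that direction were those of neuronal genes (2 of 11, 18.2%, Fisher exact p = 0.0145, adjusted p = 0.146) and endothelial markers (0 of 5, exact p = 0.0169, adjusted p = 0.146). None of the 26 tests passed an adjusted p of 0.05, and 5 had an unadjusted p under 0.05. Again the test compares those libraries, not the conditions, and loops per gene were not matched. With vehicle replicate 3 left out, the vehicle loops are those of replicate 2 alone, of which 50.8% were not in replicate 3. In that setting, patterning genes at vehicle loops not called after progesterone numbered 22 of 26 (84.6%, against 54.3% of other genes). An excess of them was thus not particular to the knockout. Without vehicle replicate 3, 3 lists passed the same exact test. Patterning genes at vehicle loops not called in the knockout numbered 19 of 28 (Fisher exact test, adjusted p = 0.000282). Early estrogen genes at those loops numbered 17 of 33 (Fisher exact test, adjusted p = 0.0447). Neuronal genes were less often than other genes at knockout loops not in vehicle replicate 2 (2 of 11, Fisher exact test, adjusted p = 0.0447).

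Loops of the knockout list alone had gene ends in both anchors more often than those of the other lists alone. Of 8069 loops called in the knockout and in no other list, 25.9% (24.9 to 26.8) had a gene start or end in both anchors, against 16.6% (15.2 to 18.0) of 2758 loops of vehicle replicate 2 alone, 18.5% (15.3 to 22.1) of 540 of vehicle replicate 3 alone and 16.7% (14.4 to 19.1) of 1002 of the progesterone list alone. In 2069 of the 8069 knockout loops (25.6%) these were ends of different genes. At 5 kb anchors the shares were 23.7% in the knockout and 12.5%, 10.7% and 11.1% in the others. Loops in all 4 lists had shares of 7.67% to 10.1%. These loops are matched across the lists, so similar shares are built in and are no control for the loops of 1 list alone. Among loops over 2 Mb, 171 of 298 knockout loops had gene ends in both anchors (57.4%, 51.6 to 63.1), against 58 of 184 (31.5%), 16 of 68 (23.5%) and 32 of 132 (24.2%) in the vehicle replicates 2 and 3 and progesterone. This property was examined after the lists were seen, and rests on 1 knockout library.

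**Figure D4:**
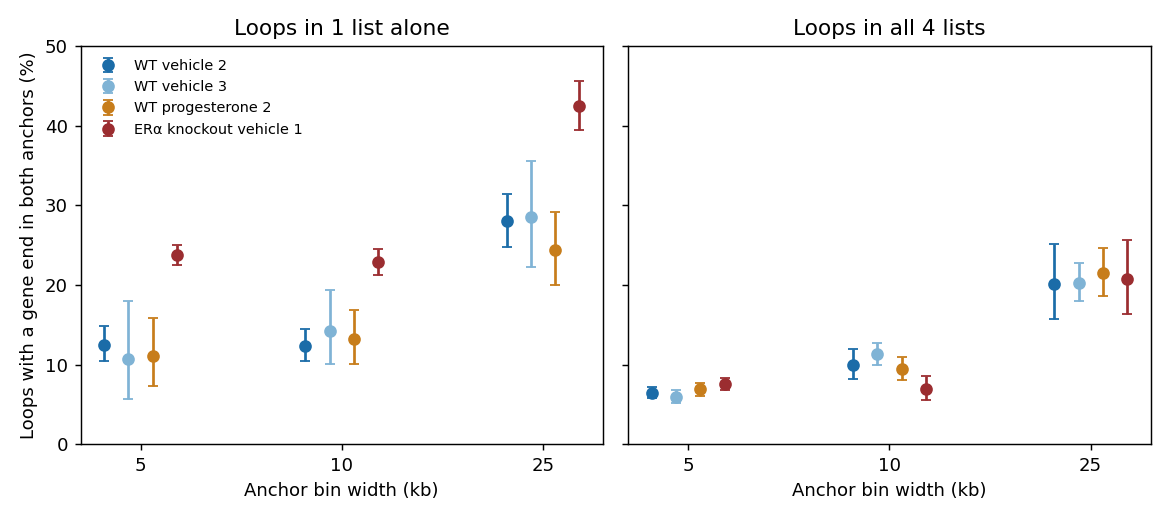
Percent of loops with a gene start or end in both anchors (vertical axis) by anchor bin width in kb (horizontal axis), for loops in 1 list alone (left) and loops in all 4 lists (right); points are libraries and bars exact binomial 95% intervals. The knockout lies above the other libraries in the left panel, with 23.7% at 5 kb against 10.7% to 12.5%, and the 4 libraries lie between 5.89% and 7.57% at 5 kb in the right panel. Loops in the right panel are matched across lists, so similar shares there are built in.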

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

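Matching by midpoints within 25 kb, vehicle replicate 3 coordinates, gene ends within 10 kb, gene bodies in loops that differ or with matched lengths, and every alternative for loops with gene ends at both anchors and for loops in exactly 2 lists were chosen after the data were seen. No paired analysis was possible because the groups share only replicate number 2 and no test compares conditions. The knockout list stayed the longest and vehicle replicate 3 the shortest at 5 kb and 10 kb, but not at 25 kb: vehicle replicates 2 and 3, progesterone and knockout held 9624, 3953, 5827 and 14153 loops at 5 kb and 4590, 3253, 3722 and 5482 at 10 kb. Overlap moved with the matching rule. For vehicle replicate 3 in progesterone, in vehicle replicate 2 and in the knockout, then progesterone in vehicle replicate 2 and in the knockout, then vehicle replicate 2 in the knockout, it was 52.8%, 59.0%, 58.1%, 58.3%, 58.5% and 55.6% with 0 kb added, 83.4%, 90.9%, 91.3%, 86.5%, 87.5% and 81.1% with 25 kb, 82.2%, 89.7%, 90.1%, 85.3%, 86.0% and 79.8% by midpoints, 80.7%, 88.6%, 87.7%, 82.9%, 84.3% and 75.0% for 5 kb loops, and 35.2%, 24.9%, 22.6%, 30.8%, 27.6% and 30.3% for 10 kb loops matched among themselves, where a loop called at another bin width is lost. Loops in both vehicle lists and not after progesterone numbered 451 at 5 kb and 350 at 10 kb, and 2027 to 6850 with a vehicle library left out; those in neither vehicle list numbered 860 at 5 kb, 3773 with 0 kb added, and 2229 to 4391 with a vehicle library left out. For the knockout, vehicle loops not called numbered 248 at 5 kb, 420 at 10 kb, 1409 with 0 kb added, 491 with 25 kb, 514 by midpoints and 1406 to 4212 with a vehicle library left out; loops in neither vehicle list numbered 3744 at 10 kb and 9632 to 13817 with a vehicle library left out. As shares of the loops in both vehicle lists, those not called after progesterone were 12.9% at 5 kb, 43.3% at 10 kb and 32.3% with 0 kb added, and those not called in the knockout were 7.08%, 51.9% and 25.5%. Bin width limits and left-out libraries change how many loops enter; for the other changes the cause was not tested. Gene lists past the threshold in loops that differ numbered 4 for progesterone with gene ends within 10 kb, and 0 to 3 for the knockout with a vehicle library left out. For loops of vehicle replicates 2 and 3, progesterone and the knockout alone, the share with genes at both anchors was 45.6%, 51.9%, 48.3% and 55.4% by gene bodies, where both anchors may lie in 1 gene, and 12.5%, 10.7%, 11.1% and 23.7% at 5 kb; with 25 kb added it was 18.0% in vehicle replicate 2, 19.3% in progesterone and 27.3% in the knockout. The knockout share was the highest of the shares given here under each of these settings. Of the percentiles of single gene lists, 194 kept their side of the threshold, 6 passed it and 8 no longer did, and of the values that answer a comparison 67 moved beyond their interval or 1.5 times the count and 44 did not. Not run, for want of contact counts, expected counts, false discovery rates or strand, were the depth rule, stricter calls and transcript start sites. Depth is unknown, so how many loops each library could have shown is too.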

Other observations

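The tests of list length, of bin width and loop length, and of gene-dense surroundings, the check by midpoints, the ratios between libraries for the gene families, the ratios of loops in exactly 2 lists, and the readings of long loops were chosen after the results were seen. Loops over 8 Mb numbered 17, 8, 11 and 50 in vehicle replicates 2 and 3, progesterone and the knockout. Hjurp, which encodes a centromere histone chaperone, was at 7 loops over 2 Mb in the knockout, among them loops to Mrpl15 (83.49 Mb), Tcea1 (83.42 Mb), Pcmtd1 (81.2 Mb) and Terf1 (72.475 Mb) on chromosome 1; the loop to Rb1cc1 (82.06 Mb) was also in vehicle replicate 2. Each wild-type library had 1 loop over 2 Mb at Hjurp, in vehicle replicate 3 one of 83.45 Mb to Lypla1, in the same region as Mrpl15 and Tcea1. The neighbours Fbxo5 and Mtrf1l, which lie near the altered gene Esr1 on chromosome 10, were at 5 such loops in the knockout. Developmental genes appeared too: in the knockout list alone, the Hoxd cluster (74675001 to 74700000) was joined with Wt1 (105125001 to 105150000) over 30.45 Mb of chromosome 2, and Wt1 with Meis2 over 10.925 Mb. On chromosome 8, a knockout loop of 31.725 Mb from Hand2 to Sall1 was matched in vehicle replicate 2, so such long loops were not particular to the knockout. Their mapping was not tested.

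On the X chromosome, a loop of 71.575 Mb from 75700001 to 147275001, whose first anchor adjoins the noncoding gene 4933407K13Rik, was in vehicle replicate 2 and progesterone. A loop of 32.45 Mb from Kdm6a at 18150001 to Firre, a noncoding gene, at 50600001 was in the progesterone and knockout lists. X-linked loops made up 1.98%, 1.97%, 2.17% and 2.48% of the 4 lists, and the interval of the knockout (2.28 to 2.69) overlaps that of progesterone (1.91 to 2.45) but not those of vehicle replicates 2 (1.78 to 2.21) and 3 (1.70 to 2.27). A loop of 16.16 Mb on chromosome 17 from 39840001, at the ribosomal RNA pseudogene Rn18s-rs5, to 56000001 was in all 4 lists.

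Loops called in exactly 2 lists showed no excess between the vehicle libraries. Vehicle replicates 2 and 3 shared 321 such loops, vehicle replicate 2 and progesterone 629.5 (mean of both directions), vehicle replicate 3 and the knockout 398.5, and progesterone and the knockout 763.5. The product of the counts of vehicle replicate 2 with progesterone and vehicle replicate 3 with the knockout, over that of the pairs that keep the vehicle libraries together, was 1.02 (0.854 to 1.23, counting error only), where a ratio below 1 would set the vehicle libraries apart. In the other pairing, vehicle replicate 2 and the knockout, the longest lists, shared 2890 and vehicle replicate 3 and progesterone, the shortest, 186, a ratio of 2.19 (1.80 to 2.67) in which list length differs between the pairs.

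The knockout list was the longest, and a deeper or more sensitive library may account for this as well as the genotype. The criterion set beforehand was that a more sensitive library should hold at least as many of the loops called in both vehicle replicate 3 and progesterone as vehicle replicate 2 did. It held fewer, 92.2% (91.6 to 92.8) against 94.0% (93.4 to 94.5), which by that criterion argues against sensitivity as the cause. The criterion was too narrow, since loss of some loops with the genotype lowers the same share in a deeper library, and the gap narrowed to 95.3% against 96.1%, still lower but with overlapping intervals, when midpoints were matched. With 1 knockout library and no depth, sensitivity and genotype cannot be told apart.

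Loops in both vehicle lists and not in the knockout list, such as the 205 kb Igf1 loop, could in part be near misses of the matching. Of these 808 loops, 47.3% (43.8 to 50.8) had a knockout loop within 25 kb of both anchors, and the interval spans the 50% set as the dividing value beforehand. Whether most are near misses therefore stays open, as does a difference of genotype, which was not tested with replicates.

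Loops of the knockout list alone had gene ends in both anchors more often than those of other lists. The mix of bin widths and loop lengths is argued against. The share was 27.5% after reweighting to the classes of vehicle replicate 2, against 16.6%. Gene-dense surroundings are not settled. After moves of 100 to 500 kb the mean share was 3.7%, against 4.69%, 6.88% and 5.87% in vehicle replicates 2 and 3 and progesterone. Moved loops kept their bin widths, however, and narrower anchors hold fewer gene ends. Loops at 25 kb made up 1033 of the 8069 knockout loops, against 735 of 2758, 189 of 540 and 357 of 1002. No moved share was matched on bin width. A criterion set beforehand, against the 25.9% observed, was dropped because loops of every list fell far below their own share. A longer list that reaches weaker loops stays open: over loops of 1 list alone, vehicle replicate 2 differed from the shorter replicate 3 by -1.95 percentage points (-5.51 to 1.61), but by 1.76 (-4.36 to 7.87) at 5 kb, and over whole lists the share rose with length, from 12.2% in vehicle replicate 3 to 13.1%, 13.3% and 18.6% in progesterone, vehicle replicate 2 and the knockout. The lists differ in their mix of bin widths. In the same order, whole-list shares were 6.55%, 9.40%, 10.3% and 16.6% at 5 kb and 22.1%, 24.6%, 26.5% and 34.1% at 25 kb. At 10 kb they were 12.3%, 11.9%, 13.2% and 17.5%. The wild-type lists thus also rose with length at 5 kb and 25 kb, but not in full order at 10 kb. Contact among genes active in every cell may contribute. Of 310 genes for ribosomal proteins, proteasome subunits, NADH dehydrogenase and initiation factors, 130 were at anchors of knockout-alone loops. That number was at the 100th percentile and 1.56 times the random mean (1.35 to 1.77). It met the criterion set beforehand, but that criterion compared the knockout with vehicle replicate 2 alone. Its comparison of shares, 41.9% against 11.3%, also follows list length, since all genes were at 27.2% against 9.83%. Vehicle replicate 3 was at 1.66 times (0.863 to 2.85, 12 genes, 95.4th percentile) and vehicle replicate 2 at 1.21 (0.860 to 1.65, 88.9th). Progesterone was at 1.10 (0.573 to 1.89, 12 genes, 64.6th). These intervals are wide and overlap that of the knockout, so the ratios do not set the knockout apart. Genotype, list length, gene-dense surroundings and the handling of this 1 library are not separated by these data.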
